A study of Mus musculus with 6 samples.

How the data were processed

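RNA was measured in 6 samples of mouse embryonic stem (ES) cells that carried a fluorescent reporter called 2C::tomato. The cells had been sorted by fluorescence into reporter-positive and reporter-negative cells, with 3 samples of each. Per the labels' protocols, the cells were grown on gelatin, total RNA was extracted on columns with DNase digestion, and 100 ng per sample was labelled with biotin for an Affymetrix whole-transcript array. The protocol also names vehicle or 4-hydroxytamoxifen (4OHT) treatment to delete Kdm1a, and the titles of all 6 samples mark them as wild type, without naming which of the treatments they received.

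The values analysed were the log2 expression values deposited by the authors, 1 column per sample. Per the submitters' processing notes they came from RMA in Affymetrix Expression Console, and RMA corrects the background, normalizes quantiles between arrays and summarises the probes of a probeset on the log2 scale. The software versions, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. RMA pulls dim probesets together, so differences of genes near the lower end of the scale can be understated. Normalizing quantiles removes any difference in total RNA between samples. Array medians over all 35556 probesets lay between 6.95 and 7.04, and the number of arrays limits the precision.

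Gene symbols came from the platform annotation. It paired 21789 probesets with 1 symbol and 1621 with several, and 12146 were not listed and stay unnamed here. Symbols were checked by gene identifier against the RefSeq genes of assembly GRCm38.p6, which was used for names and neighbour order only. Of the single-symbol probesets, 21698 matched by identifier and 0 symbols changed. Probesets with several symbols or none entered no comparison between named genes. For the 999 genes with several probesets, the one with the highest mean over all 6 arrays was used, which left 19938 genes. No dim gene was filtered out. Members of the Usp17l, Tdpoz, Pramel, Obox and Tcstv families have near-identical copies whose transcripts can bind the same probes, so their separate values are uncertain.

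Groups and replicate numbers were taken from the sample titles. Positive and negative arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 19938 genes and a threshold of 0.05. A further result required a difference of at least 2-fold beside that threshold. Errors are the SD over 3 arrays for a level and the standard error (SE) of the fit for a log2 difference, which is always positive minus negative. The labels do not say that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

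Gene lists were tested with limma's camera with its preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 23 lists. Camera compares the members of a list with all other genes. The median log2 difference over all genes was -0.043, so camera can point upward for a list whose mean is below 0. Camera was repeated with a correlation estimated per list, and limma's fry was run beside it. Members were also counted past the gene test over all genes and adjusted over the list alone. The mean of each list was compared between the groups with a two-sided exact permutation test over the 20 assignments of 3 arrays against 3, for which the smallest possible p is 0.1. This test ignores the replicate numbers. It takes the arrays as exchangeable, which arrays that vary by replicate number are not, so its p-values are a rough guide only. The lists of two-cell-stage genes and of multicopy families draw on a literature that includes work with this reporter, so their direction is not independent evidence.

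The lists, the main tests and most alternatives were fixed before the data were examined, as was the rule for naming genes. That rule took the 10 largest rises and 10 largest falls among genes past the test without overlap between the groups, and up to 3 members of each list past the test. Where none passed, it took the member with the largest difference, given as a value. It always included Kdm1a, Pou5f1, Nanog, Sox2, Zscan4c and Trim28. Because no gene passed, it named 27 genes. Zscan4c has no single-symbol probeset here and is not reported. Another 23 genes were chosen after their values were seen: Gm5662, Gm7982, Usp17la, Zfp352, Arg2, Tmem92, Pramel6, Tcstv3, Taf7l, Slc25a31, Tex101, Eda2r, Cdk1, Pgk1, Hk2, Fbxo15, Esrrb, Olfr767, Egln1, Bnip3, Tagln, Fos and Col1a1. Counts of genes at least 2-fold apart without a test, and of genes whose groups do not overlap, were also added after the data were seen.

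The replicate numbers 1 to 3 are shared by both groups, and the labels do not say what they mark. Deviations from the group mean correlated across genes between same-numbered positive and negative arrays with r = 0.55 for number 1, 0.55 for number 2 and 0.46 for number 3. The numbers were therefore treated as pairing the samples, on the evidence of the data alone. The main comparison has no block, as fixed beforehand, and a fit with the replicate number as a block is given beside it where it changes a call or moves a count by more than 1.5 times.

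The procedure was tested on simulated data with independent noise, in which 200 of 19938 genes were changed between 3 and 3 arrays. It called 54.8% of genes changed 2-fold, 90.6% of those changed 4-fold and 98.3% of those changed 16-fold, and between 3.80% and 5.39% of the calls were false. The simulated change was the same size in every positive array, while the large rises seen here differed between positive arrays. These shares therefore do not give the power for such rises. Alternatives were the replicate block, an intensity trend in the prior, median centring, a second quantile normalization, leaving out the dimmest 30% or 50% of genes, the mean of a gene's probesets, all probesets, array weights, other thresholds, a test against a 1.5-fold difference, and leaving out each array in turn. Leaving out both arrays of replicate 2 was added after the data were seen. Plots were drawn with matplotlib 3.10.9.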

Results

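Expression was measured on whole-transcript arrays in mouse ES cells sorted by the 2C::tomato reporter, 3 arrays of reporter-positive and 3 of reporter-negative cells. In published work with this reporter, the promoter of an endogenous retrovirus active in the early embryo drives a tomato fluorescent protein, and a small share of ES cells is positive at a given time. The question was which genes differ between the cells that express the reporter and those that do not. Values were log2 expression as normalized by the authors, and 19938 genes with a symbol of their own were compared. Arrays correlated with each other at r between 0.969 and 0.995 across genes, and no array was a copy of another.

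Kdm1a, the histone demethylase that can be deleted in this line, was measured first because the protocol names its deletion. Its log2 level (probeset 10517465) was 10.95 ± 0.06 (SD, n = 3) in positive and 11.07 ± 0.16 (SD, n = 3) in negative arrays. The difference of -0.12 (SE 0.12) did not pass the test (limma adjusted p = 0.918), and the 6 arrays lay between 10.91 and 11.25. Without negative array 2 the difference was -0.03. The array does not test whether an exon was removed.

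The list of two-cell-stage genes had all 18 measured members higher in positive cells, by a mean log2 difference of 2.70, and passed camera with its preset correlation but not with an estimated one (adjusted p = 0.416), while no single gene passed the test. The largest single differences, given as values, were those of Gm5662 at 40.5-fold and Gm7982 at 16.2-fold, which are not on that list, and of its members Tdpoz3 at 27.8-fold, Usp17la at 15.2-fold and Zfp352 at 12.9-fold. Leaving out positive array 2 lowered the log2 difference of Gm5662 from 5.34 to 4.10, of Gm7982 from 4.02 to 2.75, of Tdpoz3 from 4.80 to 3.58, of Usp17la from 3.93 to 2.36 and of Zfp352 from 3.68 to 2.61. Across all genes, 102 were at least 2-fold higher in positive cells and 3 were at least 2-fold lower. Of the 102, 28 were at least 4-fold and 12 at least 8-fold higher. The 3 lower genes were Acta2, Tagln and the olfactory receptor gene Olfr767. These counts rest on size alone. The sizes differed between the positive arrays: all 28 genes at least 4-fold higher had their highest level in positive array 2, then array 1, then array 3, as did 88 of the 102.

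No gene passed the test of positive against negative cells. With limma, 0 of 19938 genes had an adjusted p under 0.05 (smallest 0.910), and 0 passed that threshold with a difference of at least 2-fold. At an unadjusted p under 0.05 there were 388 genes higher and 490 lower, 878 in all. Chance gives 996.9 for arrays that can be exchanged, which arrays that vary by replicate number cannot. The other splits of the arrays 3 against 3 that part all same-numbered pairs gave 54, 438 and 44 such genes. With the replicate number as a block, 0 genes passed (smallest adjusted p 0.363), and 1076 were higher and 1318 lower at an unadjusted p under 0.05. Of the 102 genes at least 2-fold higher, 72 had all 3 positive arrays above all 3 negative arrays and 46 had an unadjusted p under 0.05. Over all genes, 813 were higher and 1426 lower without overlap, together 11.2%. Chance gives 10% for arrays that can be exchanged, which arrays that vary by replicate number cannot, and the other 3 splits of the arrays 3 against 3 that part all same-numbered pairs gave 2.5% to 7.8%. Of the 3 lower genes, Olfr767 alone had no overlap, with a log2 difference of -1.14 (SE 0.36).

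The counts by size depended on single arrays. Without positive array 2 the 102 genes at least 2-fold higher became 45, and without positive array 3 they became 182. The 72 without overlap became 40 and 148 in the same cases. Genes at least 2-fold lower numbered 26 without positive array 2, 16 without negative array 1, 7 without negative array 3, and 5 without negative array 2, positive array 1 or positive array 3. With both arrays of replicate 2 left out, 30 genes were at least 2-fold higher and 30 of that kind had no overlap, between 2 positive and 2 negative arrays.

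**Figure D1:**
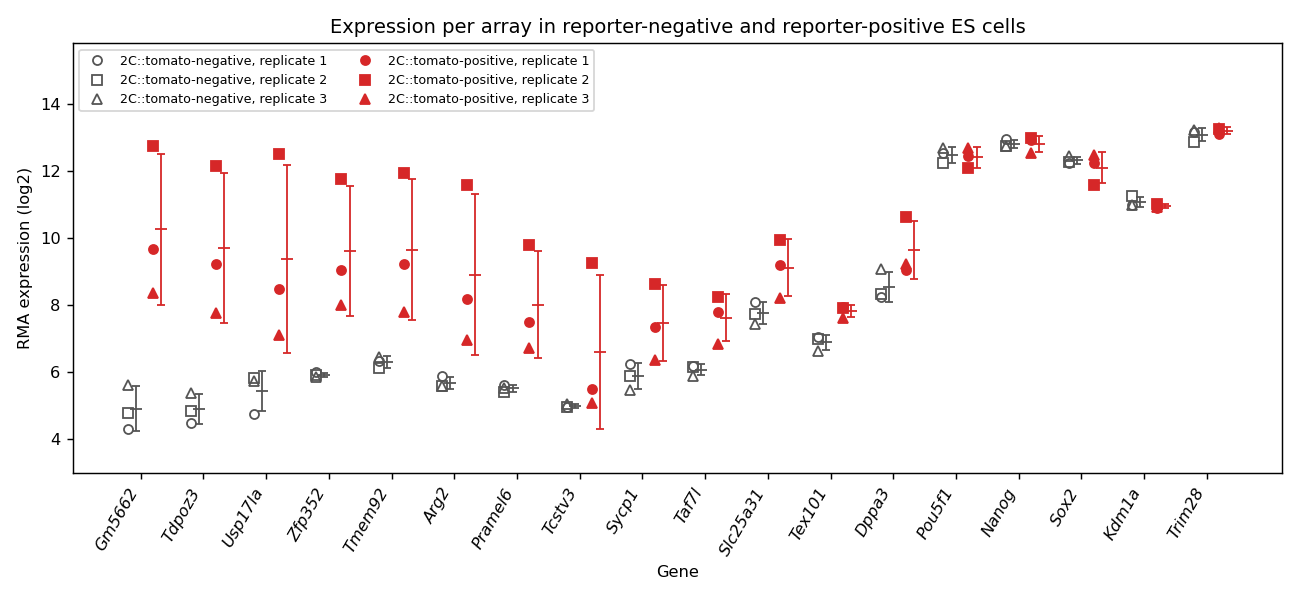
RMA expression (log2, vertical axis) of 18 named genes on each of the 6 arrays, with open grey symbols for reporter-negative and filled red symbols for reporter-positive arrays, the symbol shape giving the replicate number, and a bar for the mean ± SD of 3 arrays. For Gm5662 the positive arrays sat at 12.7, 9.67 and 8.37 and the negative arrays between 4.32 and 5.63, while Kdm1a lay between 10.91 and 11.25 on every array.

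The two-cell-stage and Zscan4-state genes, which mark the cells of the two-cell embryo and a transient state of ES cells, were higher in positive cells for 18 of 18 measured members. The list held 42 symbols, and no Zscan4 gene was among the 18 measured members, so it does not test the Zscan4 genes themselves. The mean of the list was 8.51 ± 1.97 (SD, n = 3) in positive and 5.82 ± 0.06 (SD, n = 3) in negative arrays, a log2 difference of 2.70 (median 2.88). Of the 18, 17 were at least 2-fold higher and 17 had no overlap between the groups. The list passed camera with its preset correlation (adjusted p = 1.14e-21) and not with an estimated one (adjusted p = 0.416 with an estimated correlation). Its exact permutation p was 0.1, the smallest that 3 arrays against 3 can give, in a test that ignores the replicate numbers. By replicate number, the mean difference was 2.14 in pair 1, 4.93 in pair 2 and 1.03 in pair 3, and without positive array 2 it was 1.60. Over all genes 0 members passed, and adjusted over the list alone 12 did. That count was 0 without any one of the 3 negative arrays and 18 without positive array 3. The list draws on work with this reporter and is not independent evidence.

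Among its members, Tdpoz3 (probeset 10494003), of a family of TD and POZ domain genes, had a log2 difference of 4.80 (SE 1.00). Zfp352 (probeset 10505914), a zinc finger gene, differed by 3.68 (SE 0.85), with negative arrays between 5.87 and 6.0 and positive arrays at 9.06, 11.8 and 8.01. Tmem92, a membrane protein gene, was 10.1-fold higher, Arg2, the mitochondrial arginase, 9.32-fold and Pramel6 5.62-fold. These 5 genes and Usp17la passed when adjusted over the list alone, and their limma adjusted p over all genes was 0.910. The log2 difference of Tmem92 fell from 3.34 to 2.20 without positive array 2, that of Arg2 from 3.22 to 1.88 and that of Pramel6 from 2.49 to 1.60. Tcstv3 did not pass over the list alone. It was at 9.24 in positive array 2, and at 5.51 and 5.08 in positive arrays 1 and 3, against 4.95 to 5.05 in the negative arrays.

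The multicopy families taken by symbol (Usp17l, Tdpoz, Pramel, Obox and Tcstv genes) likewise draw on work with this reporter and share 12 members with the two-cell list. Of 26 measured members, 23 were higher and 3 lower, 15 at least 2-fold higher and 15 higher without overlap. The mean log2 difference was 1.61 (median 1.47), with 1.21, 3.13 and 0.51 in pairs 1, 2 and 3, and 0.88 without positive array 2. Camera gave an adjusted p of 5.61e-15 with its preset correlation, and the list did not pass otherwise (adjusted p = 0.416 with an estimated correlation). The exact permutation p was 0.1. Adjusted over the list alone 5 members passed, 11 with the replicate number as a block, 0 without any one negative array or positive array 1, 11 without positive array 2, and 14 without positive array 3. Copies of these genes can share probes, so Usp17la, Tdpoz3, Pramel6, Tcstv3 and Gm7982, the last with 17 probesets, are uncertain as single genes. Gm5662 lay between Gm16381 and Gm5039 in gene order, which were also higher, by 1.49 and 1.88. Whether it shares probes with them was not tested, so its value is uncertain as well.

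Germline and meiosis genes were higher in positive cells for 26 of 30 measured members, 4 of them at least 2-fold and 8 without overlap. The mean log2 difference was 0.49 (median 0.37), with 0.35, 0.81 and 0.30 in pairs 1, 2 and 3. Camera gave an adjusted p of 1.67e-10 with its preset correlation (adjusted p = 0.416 with an estimated correlation), and the exact permutation p was 0.2. Over all genes 0 members passed. Adjusted over the list alone 2 did, Tex101 and Taf7l, and 12 with the replicate number as a block. The count of 2 became 0 without negative array 2, negative array 3 or positive array 1, 5 without negative array 1 and 7 without positive array 3.

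Tex101, a germ cell surface glycoprotein gene, was 1.90-fold higher, and its pairs differed by 0.89, 0.91 and 0.98. Taf7l, a germ cell form of a TFIID subunit, was 2.93-fold higher (log2 1.55, SE 0.33). Slc25a31, the ADP/ATP carrier of germ cells, was 2.57-fold and Sycp1, a protein of the synaptonemal complex, 2.98-fold higher. Neither passed over the list alone in the main comparison, and both did with the replicate number as a block. The log2 difference of Sycp1 fell from 1.57 to 0.99 without positive array 2, that of Taf7l from 1.55 to 1.25 and that of Slc25a31 from 1.36 to 0.96. The oocyte and maternal-effect list did not pass, with 12 of 23 members higher, 11 lower and a mean of 0.09 (camera adjusted p = 0.462). Its mean was below 0 without negative array 2 and with array weights. Its largest difference was that of Obox6, an oocyte homeobox gene, at 1.32 (SE 0.78), which was 3.64 in pair 2, 0.31 in pair 1 and 0.02 in pair 3, and 0.32 without positive array 2.

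Core and naive pluripotency genes did not pass, with 13 of 27 members higher and 14 lower. Their mean was 0.02 and their median -0.04, against an upward direction in camera (adjusted p = 0.433). Without positive array 2 the mean was 0.11 and the list passed camera (adjusted p = 0.0271), though with an estimated correlation over all arrays it did not pass (adjusted p = 0.848). The mean was below 0 without negative array 2, positive array 1 or positive array 3. Pou5f1, which encodes Oct4, stood at 12.40 ± 0.30 (SD, n = 3) in positive and 12.48 ± 0.24 (SD, n = 3) in negative arrays, a difference of -0.08 (SE 0.19). Nanog differed by 0.01 (SE 0.15) and Sox2 by -0.22 (SE 0.23). The sign of Nanog turned with median centring and without negative array 2, negative array 3, positive array 1 or positive array 2, with values down to -0.08. Without positive array 2 Sox2 differed by 0.04 and Pou5f1 by 0.07, and without negative array 3 Pou5f1 differed by 0.02. By pair Pou5f1 differed by -0.10, -0.14 and -0.01. The largest difference of the list was that of Dppa3, a maternal factor of the oocyte and early embryo, at 1.10 (SE 0.44). Fbxo15 differed by 0.75 (SE 0.37) and Esrrb, a transcription factor of naive ES cells, by -0.36 (SE 0.17), and none of these genes passed the test. They differed by 0.60, 0.34 and -0.18 without positive array 2.

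Transcriptional co-repressors and silencing genes did not pass, with 19 of 32 members higher, 13 lower and a mean of 0.01 (camera adjusted p = 0.329). That mean lay below 0 with median centring, with a second quantile normalization and without negative array 2, positive array 1 or positive array 3. Resf1, a retroelement silencing factor, had the largest difference, 0.36 (SE 0.18), without overlap, and 0.16 without negative array 2. Trim28, a co-repressor that silences endogenous retroviruses, differed by 0.12 (SE 0.13), by 0.01 without negative array 2 and by -0.03 with array weights. The DNA methylation machinery did not pass either, with 6 of 9 members higher and a mean of 0.02 (camera adjusted p = 0.503), which was -0.0078 without negative array 2, -0.05 without positive array 3 and 0.11 without positive array 2. Dnmt3l, a cofactor of the de novo methyltransferases, differed by 0.25 (SE 0.19), and by 0.08 without negative array 2, 0.39 without positive array 2 and 0.15 without positive array 3. By pair Dnmt3l differed by 0.14, 0.31 and 0.31.

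In the main comparison, none of the lists for other lineages passed camera at its preset correlation. Primitive and visceral endoderm genes were lower for 17 of 24 members, with a mean of -0.16 (median -0.23, camera adjusted p = 0.0589), and Gata4, an endoderm transcription factor, differed by -0.46 (SE 0.29), and by -0.79 without positive array 2 and -0.28 without positive array 3. This list passed without negative array 2 (mean -0.20, adjusted p = 0.0239) and without positive array 2 (mean -0.23, adjusted p = 0.000424), and also with median centring (0.0480), a second quantile normalization (0.0129), all probesets (0.0234), array weights (0.00629) or both replicate 2 arrays left out (3.69e-05). It did not pass with an estimated correlation (adjusted p = 0.615), nor without positive array 3, where its mean was -0.08. Trophectoderm and trophoblast genes were lower for 14 of 24 members, with a mean of -0.03 and a median of -0.10, while camera pointed upward (adjusted p = 0.558). That mean was 0.08 without negative array 2, 0.09 without positive array 3 and -0.16 without positive array 2. Krt7, a keratin of simple epithelia, differed by -0.54 (SE 0.61), and between -1.15 without positive array 2 and -0.07 without negative array 2 when 1 array was left out, with pairs at -0.28, -0.23 and -1.09. With the replicate number as a block, 2 endoderm and 6 trophectoderm members passed over the list alone, against 0 of each without it. The primed epiblast and early somatic list had 10 of 22 members higher, a mean of 0.03 and a median of -0.05 (camera upward, adjusted p = 0.832), and its mean was -0.01 without positive array 3. Its largest difference was that of Otx2, a transcription factor of the primed epiblast, at 0.68 (SE 1.06), which was -0.11 without negative array 2 and -0.05 without positive array 3, with pairs at 0.91, -0.02 and 1.14. The Rhox cluster of reproductive homeobox genes had 6 of 8 members lower and a mean of -0.09 (camera adjusted p = 0.265), with Rhox13 at 0.59 (SE 0.24). That mean was 0.0013 without negative array 1, -0.21 without negative array 2 and -0.17 without positive array 1. Rhox13 differed by 0.36 without positive array 2.

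Fibroblast feeder genes, markers of cells that ES cultures can carry, were lower for 17 of 24 members, 5 of them without overlap. Their mean was -0.20 (median -0.18, camera adjusted p = 0.0883), and -0.19, -0.04 and -0.36 in pairs 1, 2 and 3. With the replicate number as a block the list passed camera (adjusted p = 0.0394), and not with an estimated correlation (adjusted p = 0.638 with an estimated correlation and the block). Without positive array 2 its mean was -0.40 and it passed (adjusted p = 0.000230), as it did without the dimmest 30% of genes (0.0418), with all probesets (0.0383), with array weights (0.0194) and without both replicate 2 arrays (0.000908). It did not pass without negative array 2 (mean -0.07) or positive array 3 (mean -0.06). Acta2, smooth muscle actin, differed by -1.16 (SE 1.06) and Tagln, transgelin, by -1.13 (SE 1.06), while Col1a1, a fibrillar collagen, differed by -0.41 (SE 0.15) without overlap. Acta2 and Tagln were highest in replicate 2 of both groups, at 11.82 and 10.96 in negative array 2 and at 11.21 and 9.86 in positive array 2. They differed by -2.24 and -2.10 without positive array 2, and by -0.34 and -0.17 without negative array 2. By pair Acta2 differed by -0.71, -0.60 and -2.15 and Tagln by -0.34, -1.10 and -1.93.

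Cell division genes were slightly higher in positive cells, with 19 of 21 members higher and 5 of them without overlap. The mean log2 difference was 0.14 (median 0.14), with 0.12, 0.23 and 0.08 in pairs 1, 2 and 3, and 0.08 without positive array 2. The list passed camera with its preset correlation (adjusted p = 3.00e-06) and not otherwise (adjusted p = 0.416 with an estimated correlation), and its exact permutation p was 0.1. Cenpe, a kinesin of the centromere, differed by 0.35 (SE 0.14) and Cdk1, the mitotic kinase, by 0.28 (SE 0.13), with 0 members past the test over all genes or the list alone. Leaving out positive array 2 made these 0.23 and 0.18. DNA replication genes were lower for 20 of 24 members, with a mean of -0.09, and did not pass (camera adjusted p = 0.220). They passed without negative array 1 (mean -0.11, adjusted p = 0.0251), with a second quantile normalization (adjusted p = 0.0167) and without the dimmest 50% of genes (adjusted p = 0.00605), and not with an estimated correlation (adjusted p = 0.808). They did not pass without positive array 2, where the mean was -0.04. Cdc6, which licenses replication origins, differed by -0.40 (SE 0.12) without overlap.

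Apoptosis and p53 target genes were higher for 15 of 19 members, with a mean of 0.19 (median 0.17) and 0.20, 0.29 and 0.09 in pairs 1, 2 and 3. Camera gave an adjusted p of 0.000289 with its preset correlation (adjusted p = 0.416 with an estimated correlation), and the exact permutation p was 0.3. Without positive array 2 the mean was 0.07 and the call was lost (adjusted p = 0.138). Adjusted over the list alone 0 members passed, and 5 with the replicate number as a block. Btg2, an antiproliferative p53 target, differed by 0.62 (SE 0.44), Eda2r, a receptor of the TNF family, by 0.51 (SE 0.15) and Sesn2, a sestrin, by 0.43 (SE 0.14), the last 2 without overlap. Btg2 differed by 0.12 without positive array 2, which leaves negative array 2 without its partner. By pair Btg2 differed by 0.48, 1.07 and 0.33.

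Glycolysis genes were lower in positive cells for 15 of 18 members. The mean log2 difference was -0.18 (median -0.17), with -0.12, -0.24 and -0.17 in pairs 1, 2 and 3. The list passed camera with its preset correlation (adjusted p = 0.0407) and not otherwise (adjusted p = 0.445 with an estimated correlation), and its exact permutation p was 0.1. The call was lost without negative array 2 (mean -0.19, adjusted p = 0.108), negative array 3 (mean -0.14, adjusted p = 0.162) or positive array 1 (mean -0.19, adjusted p = 0.0766), while the mean stayed below 0 without any one array. Pdk1, a kinase that inhibits pyruvate dehydrogenase, differed by -0.78 (SE 0.41), Pgk1, phosphoglycerate kinase, by -0.31 (SE 0.16) and Hk2, a hexokinase, by -0.31 (SE 0.15), with 0 members past the test over all genes or the list alone. Leaving out positive array 2, which leaves negative array 2 without its partner, made these -0.28, -0.20 and -0.19. By pair Pdk1 differed by -0.42, -1.48 and -0.45, Pgk1 by -0.35, -0.31 and -0.28 and Hk2 by -0.34, -0.34 and -0.24.

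Lists of the respiratory chain and of RNA and protein synthesis did not pass. Nuclear genes of oxidative phosphorylation had 12 of 26 members higher and a mean of -0.02, with camera upward (adjusted p = 0.801), and Ndufa1, a complex I subunit, differed by 0.28 (SE 0.13), and by 0.16 without negative array 1. The mean of this list was above 0 with array weights and without both replicate 2 arrays. Cytosolic ribosomal proteins were higher for 20 of 27 members, with a mean of 0.03 (camera adjusted p = 0.106), and Rps9 differed by 0.29 (SE 0.16), and by 0.18 without positive array 2. That list passed without negative array 2 (mean 0.07, adjusted p = 0.0197) or positive array 1 (mean 0.09, adjusted p = 0.00127) and with an intensity trend in the prior (adjusted p = 0.0327), not with an estimated correlation (adjusted p = 0.808), and its mean was below 0 without negative array 1 or positive array 2. Ribosome biogenesis had 9 of 23 members higher and a mean of -0.03 with camera upward (adjusted p = 0.801), and Rrp9, of the U3 small nucleolar particle, differed by -0.22 (SE 0.16), and by -0.06 without positive array 2. Without positive array 2 the mean of the list was 0.08 and it passed (adjusted p = 0.0346), though with an estimated correlation over all arrays it did not pass (adjusted p = 0.940). Its mean was also above 0 without negative array 1, negative array 3 or both replicate 2 arrays. Splicing factors had 8 of 21 members higher and a mean of -0.03 with camera upward (adjusted p = 0.801). Srsf2, their largest difference, was at -0.19 (SE 0.24), and at 0.07 without positive array 2. The mean of that list was 0.03 without positive array 2 and also above 0 without negative array 3 or both replicate 2 arrays.

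Stress and interferon lists did not pass. Endoplasmic reticulum and amino acid stress genes had 12 of 23 members higher and a mean of 0.05 (camera adjusted p = 0.0781), led by Sesn2, and passed without negative array 3 (mean 0.08, adjusted p = 0.0317), though not over all arrays with an estimated correlation (adjusted p = 0.416). The mean of this list was 0.02 without negative array 2, where it did not pass. Immediate-early and heat-shock genes had 13 of 20 members lower and a mean of -0.12 (camera adjusted p = 0.433), which was 0.0069 without negative array 2 and -0.22 without negative array 1. Their members went both ways, with Hspa1a, the inducible Hsp70, at 1.05 (SE 0.42) and Fos at -0.60 (SE 0.90), the latter 0.31 without negative array 2, which leaves positive array 2 without its partner. By pair Fos differed by -0.26, -0.92 and -0.61. Interferon-stimulated genes had 13 of 25 members higher and a mean of -0.00186, with camera upward (adjusted p = 0.948), and that mean was above 0 with a second quantile normalization, without the dimmest 30% or 50% of genes and without negative array 2, positive array 1 or positive array 3. Stat2, a transducer of interferon signals, differed by 0.53 (SE 0.50), and between 0.06 without positive array 2 and 0.92 without negative array 2 when 1 array was left out, with pairs at 0.46, 0.72 and 0.42.

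In all, 6 of the 23 lists passed camera with its preset correlation, 5 upward and 1 downward. With the replicate number as a block 7 passed, with an estimated correlation 0, and with fry 0. Of the 10 ways to split the 6 arrays 3 against 3, 6 gave at least 6 lists with the preset correlation, the real split included.

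**Figure D2:**
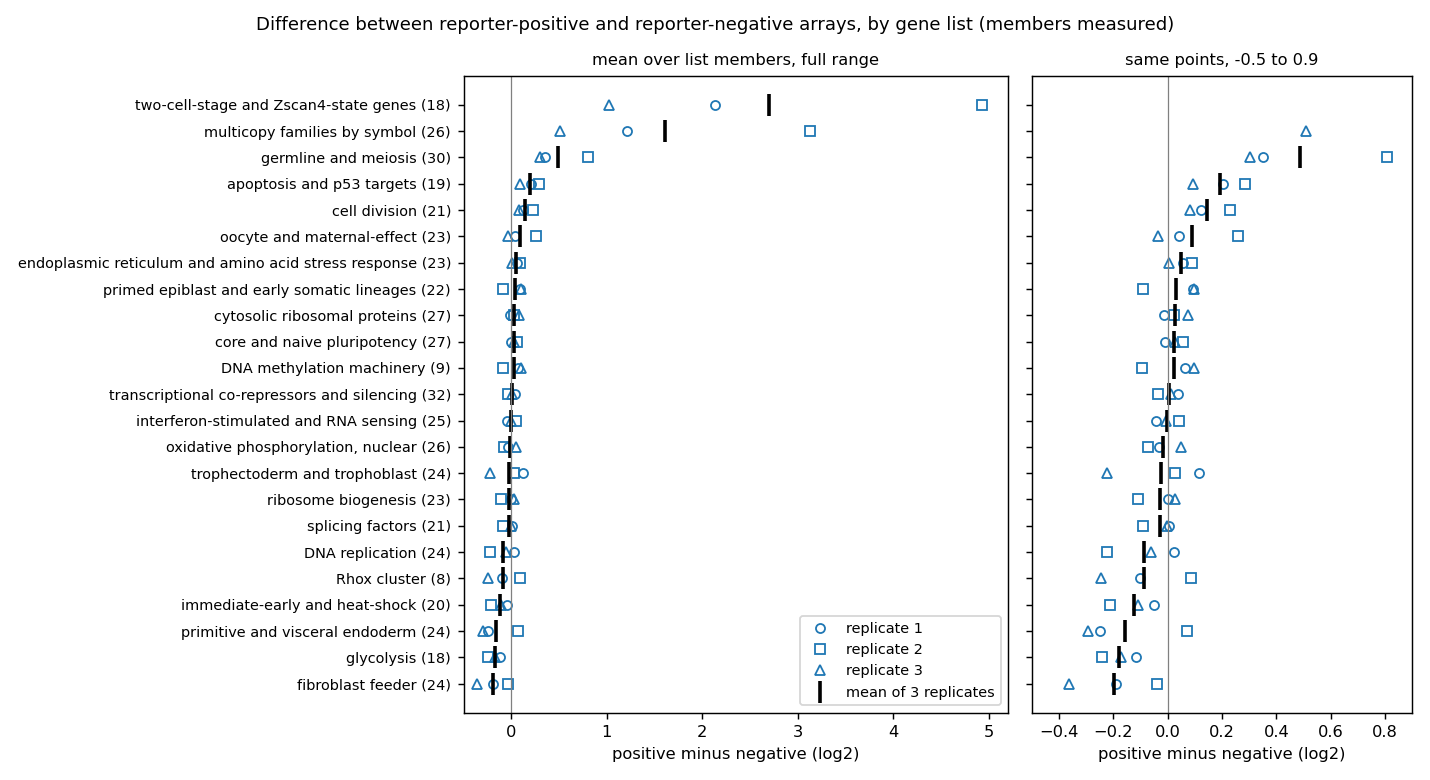
Mean log2 difference of positive minus negative arrays (horizontal axis) for the 23 gene lists, with the members measured in brackets, an open symbol for each same-numbered pair and a black bar for the mean of 3, at full range on the left and between -0.5 and 0.9 on the right. The two-cell list lay at 2.14, 4.93 and 1.03 in pairs 1, 2 and 3, the germline list at 0.35, 0.81 and 0.30 and the glycolysis list at -0.12, -0.24 and -0.17.

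Replicate 2 stood apart from replicates 1 and 3 in both groups. The first principal component held 56.0% of the variance and placed positive array 2 at 53.7, negative array 2 at 19.6 and the other arrays between -24.6 and -12.7. Genes at least 2-fold higher in replicate 2 than in the mean of the other replicates, in both groups, numbered 199, and 96 were at least 2-fold lower. The same counts were 36 and 22 for replicate 1 and 6 and 16 for replicate 3. Acta2, Tagln and Fos were higher in replicate 2, by 2.85, 2.90 and 2.49 on the log2 scale averaged over both groups, and Otx2 differed by -2.89.

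**Figure D3:**
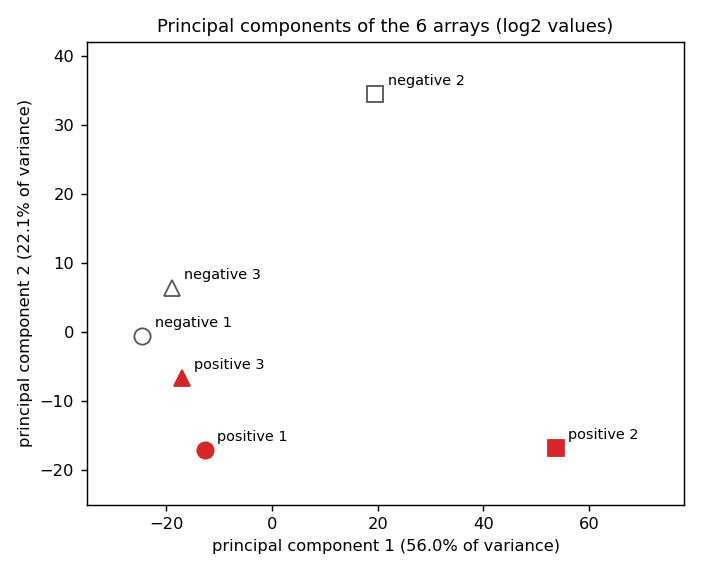
First and second principal components of the 6 arrays, from log2 values, each axis giving its share of the variance, with open grey symbols for negative and filled red symbols for positive arrays and shape by replicate number. Positive array 2 lay at 53.7 and negative array 2 at 19.6 on the first component, and the other arrays lay between -24.6 and -12.7.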

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

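The tests of array scaling, of signal shared between gene copies and of one share of cells, and their bounds, were chosen after the results were seen, as were the splits for the counts of 0 genes. The splits for the gene lists and for the genes at least 2-fold apart were written before their results, although the count of genes at least 2-fold apart was itself added after the data were seen.

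Probesets that entered no comparison of named genes also differed between the groups, above the level in all negative arrays. Of the 1621 probesets paired with several symbols, 81 (5.0%) were at least 2-fold higher in positive cells without overlap and 0 were lower. The largest of these log2 differences was 4.96. Of the 12146 probesets without a symbol, 142 (1.17%) were higher in the same way and 2 lower, up to a log2 difference of 4.32. Among the tested genes 72 of 19938 (0.361%) were higher. The difference between these shares was not tested, and 1 transcript from a multicopy family can be counted on several probesets. Of the 81 probesets, 80 were highest in positive array 2 and lowest in positive array 3, as were 48 of the 142.

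Over the 72 genes at least 2-fold higher without overlap, positive array 2 exceeded the mean of positive arrays 1 and 3 by a median of 2.61 on the log2 scale. Of these genes, 26 were set aside as multicopy by symbol, a wider choice than the list of multicopy families. It added Spopfm, Eif4a3l and Nat8f genes, BC147527, Zfp353 and all numbered Gm genes. In the other 46 genes, array 2 exceeded array 1 by a median of 1.93, but they were picked for their difference. Symbols do not show which probesets share probes, so signal shared between copies cannot be told apart. The median over all genes, -0.0426, does not test scaling of array 2, because quantile normalization holds array medians close together whatever the scaling was. A factor common to all genes of array 2 would be removed by that step, and scaling that differs between genes was not tested. If the positive samples differed only in their share of two-cell-state cells, the excess over the mean of the negative arrays in positive array 1, as a percentage of that in array 2, would be alike for every gene. Over members more than 0.5 (log2) above every negative array in positive array 2, the median was 12.6% for the two-cell list (18 members, 2.38% to 25.8%) and 31.0% for the germline list (15 members, -8.77% to 135%), 1.30 apart on the log2 scale, and within the two-cell list the log2 ratio had an interquartile range of 0.874. Each percentage rests on 1 array over another and members of a list vary together (estimated correlation 0.955 and 0.295), so one share of cells cannot be told apart from other differences between the samples for either list.

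The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes past the test and 0 with a 2-fold difference as well, all 10 splits gave at least as many, and the highest other gave 0. It gave 6 gene lists past camera with the preset correlation, 6 splits gave as many, and the highest other gave 8. It gave 105 genes at least 2-fold apart in either direction, 5 splits gave as many, and the highest other gave 222. The 4 other splits with more than 105 such genes, from 162 to 222, all kept both replicate 2 arrays on one side, which points to a structure of the samples beside the reporter. Among the 4 splits that part all 3 pairs, the other 3 gave at most 6 lists and at most 73 genes at least 2-fold apart.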

How the results depend on the processing

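Leaving out both arrays of replicate 2, the counts by size alone and the repeats of the counts over a list alone were added after the data were seen. Under all 18 alternatives run for it, limma called 0 genes, with 291 to 4851 genes at an unadjusted p under 0.05. The 4851 came with array weights, and 2394 with the replicate number as a block. The array weights were 6.21 for negative array 3, 0.29 for negative array 2 and 0.27 for positive array 2. Among the negative arrays that fit therefore rested mostly on array 3. The smallest adjusted p of any of the 50 named genes under any alternative was 0.0673, with array weights. Of 787 values of named genes under the alternatives 771 kept their direction and stayed short of the threshold, and 16 changed sign. Of 435 values of gene lists 391 kept their side of the threshold, 21 became calls, 22 lost a call and 1 reversed. The log2 difference of Kdm1a stayed below 0 throughout. Signal over background was not analysed here, so the limit for dim genes is not known. Except where a value here shows otherwise, the cause of a change was not tested.

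Genes at least 2-fold higher numbered 102. They became 41 without the dimmest 50% of genes, where fewer genes were tested, 405 over all probesets, where more were, 30 without both replicate 2 arrays, and 45 to 182 when 1 array was left out. Those without overlap, 72, became 24, 324 and 30 in the same cases, 45 with array weights, and 40 to 148 with 1 array left out. The 3 genes at least 2-fold lower became 6 over all probesets, 7 with array weights and 5 to 26 with 1 array left out. With 1 array left out, the lowest counts of higher genes and the 26 lower genes came without positive array 2, the highest counts of higher genes without positive array 3.

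The 6 gene lists that passed camera became 0 with an estimated correlation, 0 with fry and 0 without both replicate 2 arrays with an estimated correlation. Other alternatives gave 6 to 9. With the replicate number as a block 7 lists passed, the fibroblast feeder list being added, and no gene or Kdm1a passed over all genes. Over a list alone the block raised counts in several lists, with 6 trophectoderm, 2 endoderm and 5 apoptosis and p53 members against 0 of each without it.

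Adjusted over the list alone, the 12 members of the two-cell list became 6 without the dimmest 50% of genes and 0 to 18 with 1 array left out. The 2 members of the germline list became 12 with the replicate block, 13 with array weights, 4 without both replicate 2 arrays, 1 over all probesets, 0 without the dimmest 50% and 0 to 7 with 1 array left out. The 5 multicopy members became 11 with the replicate block, 11 with array weights, 12 without both replicate 2 arrays, 10 with median centring, 3 without the dimmest 50%, 1 with the mean of probesets and 0 to 14 with 1 array left out. They became 0 with an intensity trend in the prior, 0 with a second quantile normalization and 0 over all probesets.

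Sign changes concerned genes and lists that had not passed a test over all arrays. Nanog differed by -0.00072 with median centring and by -0.11 without both replicate 2 arrays, and Trim28 by -0.034 with array weights and -0.0083 without both replicate 2 arrays, where Sox2 differed by 0.017. With 1 array left out, Nanog ranged from -0.077 to 0.14, Sox2 from -0.40 to 0.045, Pou5f1 from -0.22 to 0.075, Srsf2 from -0.38 to 0.071, Otx2 from -0.11 to 1.82 and Fos from -1.34 to 0.31. The mean of the ribosome biogenesis list ranged from -0.095 to 0.080, and altogether 12 of the 23 lists had a mean that changed sign when 1 array was left out, 0 of which had passed camera over all arrays. Leaving out positive array 2 moved 31 of the 50 named genes by more than 1.5 times, 24 of them toward or past 0. This also leaves negative array 2 without its partner, so a gene whose pairs are alike can be counted. Pgk1, with pairs at -0.35, -0.31 and -0.28, is an example.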

Other observations

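The tests of array scaling and of fibroblast genes in replicate 2 were chosen after the result was seen. The tests of neighbouring genes, of hypoxia-response genes and of SRF-target genes were written before their results, the last after Acta2, Tagln and Fos had been seen.

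Genes that were higher in positive cells lay near each other in the genome more often than random genes. Of the 72 genes at least 2-fold higher without overlap, 24 had another of the 72 within 5 measured genes in the RefSeq order of assembly GRCm38.p6. The highest count in 10000 random gene sets was 14 (permutation p = 1e-04, the smallest these sets can give). With 1 gene kept per symbol stem, except that every numbered Gm gene was kept, 13 of 60 did. The highest random count was 12 (permutation p = 1e-04, again the smallest possible). The neighbours Gm16381, Gm5662 and Gm5039 are all among the 13, and a count with the Gm genes reduced was not made. Examples chosen after they were seen were Tmem92 beside Gm11545 and A430060F13Rik, Gm5662 beside Gm16381 and Gm5039, and Tcstv3 beside AF067061 and BC147527. Related copies with different symbols may make up part of the 13, so shared regulation of neighbours and signal shared between copies both stay open.

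Egln1, an oxygen-sensing prolyl hydroxylase, differed by -0.73 (SE 0.17) and Bnip3, a mitophagy receptor, by -0.63 (SE 0.16), both lower without overlap and both known targets of hypoxia signalling. Neither passed the test (limma adjusted p = 0.910), and both were chosen after their values were seen. A hypothesis was that the lower glycolysis genes belong to a wider fall of hypoxia-response genes. Over 22 other hypoxia-response genes the mean change was -0.0909, at percentile 2.83 of 10000 random lists matched on level. The bound set beforehand was percentile 2.5, so the value missed it narrowly. That bound would have counted against the hypothesis, and the reading was widened to undecided only after the value was seen. By pair the mean was -0.04, 0.02 and -0.25, and camera gave an unadjusted p of 0.287, so these data lend the hypothesis no weight.

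Replicate 2 differed at least 2-fold from the other replicates in both groups for 199 genes higher and 96 lower. The median over all genes, -0.0579, does not test scaling of its arrays, because quantile normalization holds array medians close together. A factor common to all genes of an array would be removed by that step, and scaling that differs between genes was not tested. Fibroblasts stay open as well: the 24 genes of the fibroblast feeder list had a median deviation of 0.115, with 16 higher and 5 by more than 1, and without Acta2 and Tagln members ranged from -0.32 to 2.36 around a median of 0.0443, while 9 collagen and matrix genes had a median of 0.0454, and the 3 members with the highest level, Fn1, Vim and Ccn2 (picked by level after the data were seen), deviated by -0.01, 0.21 and 0.41. Genes known as targets of serum response factor (SRF) in the cytoskeleton were higher in replicate 2, with a median deviation of 0.383 over 23 members that leave out Acta2, Tagln and Fos. This lay above all 10000 random lists matched on level, whose central range was -0.149 to 0.133. Members of such a list can vary together, which random genes do not, and the list was drawn up after those 3 genes were seen. The comparison therefore describes replicate 2 and does not weigh a cause. The deviation was 0.470 in negative and 0.348 in positive cells. Whether growth or handling differed between replicates was not tested, and what set replicate 2 apart stays open.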
